A study of Homo sapiens and Mus musculus with 7 samples.

How the data were processed

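Universal protein-binding microarrays of 7 transcription factors were used, with 1 array per factor. Factors and concentrations were taken from the sample labels. Per the labels' protocols, EGR1, GATA1 and TCF3 carried a GST tag, E2F7, MITF and Stat3 a 6xHis tag and FOXO3 a Flag tag, and each was detected with a dye-coupled (Alexa) antibody to its tag. E2F7, EGR1 and Stat3 were DNA-binding domains, and Stat3 was phosphorylated, per the labels. FOXO3 was immunoprecipitated from human 293 cells.

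The spot table of each array holds 45220 spots with a brightness column for the antibody's dye. These intensity values are deposited on a linear scale, and how the authors combined or corrected scans is not given in the sources used here. On the E2F7, FOXO3, MITF and TCF3 arrays some intensities exceed the 16-bit ceiling of a scanner (734 spots for FOXO3), while on the EGR1, GATA1 and Stat3 arrays values stop at it. The Cy3 column, which would report the amount of double-stranded DNA per spot, holds the value 1 throughout and was not used. A sequence of 60 bases, made of 36 variable bases and a 24-base primer site, is given for 43796 spots. Of these, 41944 belong to the word-covering (de Bruijn) design and 1852 are control spots of 406 sequences. Spots with a flag of -100 were left out, which removed 1651 design spots for EGR1 (3.94%), 7759 for GATA1 (18.5%) and 15 for MITF. The removed spots had a median intensity of 819 for EGR1 and 533 for GATA1.

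The 8-mer table of each array lists 32896 8-mers, each standing for itself and its reverse complement. The authors deposited 3 values per 8-mer, which the file headers name as an E-score, a median intensity and a Z-score. The E-score is a rank-based enrichment score between -0.5 and 0.5. The formulas are not stated per the file headers. To learn what the deposited scores rest on, E-scores were recomputed from the spots by comparing the brighter part of the spots with an 8-mer to the brighter part of the rest. Words were read from base 2 of the probe to the end of the variable bases. Across 8-mers the deposited E-scores correlated with those recomputed from the spot intensities at an r of 0.718 for E2F7, 0.764 for TCF3, 0.812 for MITF and 0.887 for Stat3, and above these values for the others. After each spot was divided by the median of the 15 by 15 spots around it, r was 0.988 for E2F7 and at least 0.997 for the others. The deposited E-scores were used for all 8-mer results and the deposited intensities, without this division, for all spot tests.

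An 8-mer was called bound above an E-score of 0.45. The same count was taken after 20 shuffles of spot signals over sequences. The site classes, core sites, tests, thresholds, main settings and most of the other settings tried were chosen before the data were examined. A member of a class holds its sequence on either strand. The median E-score of a class was placed among 10000 random sets of as many 8-mers with the same G+C counts. Members of a class share bases and spots, which random sets do not, so the percentile is a description and not a test. The same classes were scored on every array, and bound lists were compared in 21 pairs with the overlap of independent lists of the same sizes. E-scores of 8-mers are ranks within an array, which allows levels of differing concentration and antibody to be set side by side but gives no test between factors.

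For single-base changes, the mean log2 intensity of design spots holding a core was compared with that of spots holding the changed core and not the core. Cores were TTCCCGC, GTGGGCG, GTAAACA, AGATAAG, TCACGTG, TTCCNGGA and CACCTGC in the order E2F7, EGR1, FOXO3, GATA1, MITF, Stat3 and TCF3. A two-sided permutation test with 100000 resamples was used, whose smallest p is 1e-05, with Benjamini-Hochberg adjustment over 147 tests. Intervals are 95% bootstrap intervals over spots from 10000 resamples. E-boxes on the MITF and TCF3 arrays (20 tests) and gaps of the TTC and GAA arms on the Stat3 array (3 tests) were tested in the same way against spots with none of the sites compared. No test was made between factors, since each has 1 array. All p-values measure the spread between spots of that array.

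The items named in the text are, per factor, the 5 8-mers of highest E-score (ties by Z-score), all fixed classes, the 3 largest and 2 smallest falls among single-base changes, and per pair of factors the 3 shared 8-mers with the highest lower score. C6T of EGR1 and C7A of TCF3 are named outside this rule, chosen after their values were seen.

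The other settings fixed in advance were E-score thresholds of 0.40 and 0.48, a Z-score above 4, E-scores recomputed with and without the neighbourhood division or from separate blocks of array rows, linear intensities, medians over spots, intensities divided by the neighbourhood, ordinary least squares of log2 intensity on counts of 6-mers, sites within the 18 variable bases far from the slide, and spots with flags kept. Least-squares p-values used the normal-theory model over all spots of an array. Added after seeing the data were E-scores without control sequences and the tests of E-boxes and of gaps on spots with no other such site.

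The procedures were tested on simulated signals over the FOXO3 array's sequences. Over 20 draws of 21 changes, a fall of -0.25 on the log2 scale was called in 97.1% of tests, a fall of -1 in 100% and no change in 2.14%. The noise had the standard deviation of the FOXO3 design spots, 0.532. That of core spots was higher on every array. It was 1.47 for GATA1 and MITF, 1.37 for TCF3, 1.11 for Stat3, 0.90 for E2F7, 0.70 for FOXO3 and 0.63 for EGR1. Spots with a changed EGR1 core had up to 2.02 (G5C). The rate for small falls therefore does not hold for GATA1, MITF and TCF3 and was not shown for the other arrays. Without any difference, 3% of 200 permutation tests had p under 0.05. Of 20 8-mers planted among 32896, 20 passed the E-score threshold, 18 when a trend over array rows was added and 20 again after the neighbourhood division, and 0 passed with nothing planted. The planted effect was made smaller after a larger size was recovered in full even under the trend. Simulated least-squares contrasts correlated with the true ones at an r of 0.902 over 21 changes, and 21 of 21 lay within 2 standard errors. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.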

Results

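The binding of 7 transcription factors to DNA was measured on universal protein-binding microarrays. These are glass slides carrying double-stranded probes whose variable parts together hold all short DNA words. A tagged protein binds the probes, a fluorescent antibody to the tag is added, and the brightness of each spot reports how much protein its probe retained. The factors were E2F7 at 500 nM, EGR1 at 300 nM, FOXO3 at 100 nM, GATA1 at 65 nM, MITF at 100 nM, Stat3 at 400 nM and TCF3 at 100 nM. Stat3 was the mouse protein and the others were human. Each factor had 1 array, so no value has a replicate array, and differences in concentration, construct, tag and antibody accompany each difference between factors.

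Each array carried 41944 spots of the word-covering design. The median spot intensity was 7233 for E2F7, 6742 for EGR1, 29768.5 for FOXO3, 767 for GATA1, 6646 for MITF, 3870 for Stat3 and 1376 for TCF3. The 99th percentile stood 67.6 times above the median on the GATA1 array and 2.51 times above it on the FOXO3 array. On the EGR1 array 4.63% of the spots used lay at the 16-bit ceiling of the scanner, and 0.582% did on the GATA1 array. Values at the ceiling understate the signal of the brightest words and sites on these arrays. A typical 8-mer was present in a median of 36 spots, or 34 on the EGR1 array and 29 on the GATA1 array. A homeodomain control probe printed in 50 copies, of which 46 were used on the EGR1 array and 39 on the GATA1 array, had a coefficient of variation between 7.63% on the Stat3 array and 37.2% on the EGR1 array.

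The question asked of each array was which DNA words its factor prefers. An 8-mer was called bound when its deposited enrichment score (E-score), which runs from -0.5 to 0.5, exceeded 0.45. This threshold was passed by 72 of the 32896 8-mers for E2F7, 78 for EGR1, 110 for FOXO3, 175 for GATA1, 63 for MITF, 92 for Stat3 and 121 for TCF3. After spot signals were shuffled over probe sequences, 0 8-mers passed in any of 20 shuffles of any array, and the highest shuffled E-score was 0.426, on the GATA1 array.

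E2F7 is an atypical member of the E2F family, repressors and activators of cell-cycle genes that read TTSSCGC sites. Of its best words, CGCGGGAA had an E-score of 0.497 and a median intensity 2.31 times that of the median 8-mer, and GCGGGAAA had 0.496 and 2.37 times. GGCGGGAA had 0.495. TCCCGCCA, with 0.496, and GCGCGGGA, with 0.493, lie outside the site classes. Among the E2F site classes chosen before the data were examined, TTCCCGC had 6 of its 8 member 8-mers bound, with a median E-score of 0.474. TTGGCGC and TTCGCGC had 4 of 8 bound each, with medians of 0.4504 and 0.4503. TTGCCGC had 0 of 8, with a median of 0.323. Each of these medians exceeded those of all 10000 random sets of 8-mers with the same G+C counts, a description only, since class members share spots. The 4 classes held 14 of the 72 bound 8-mers. When E-scores were recomputed from the spot intensities without correction for position on the array, 13 8-mers passed for E2F7, with 1 of 8 left for TTGGCGC and 0 of 8 for TTCGCGC. After the neighbourhood division 83 passed and 71 of the 72 recurred, with 4 of 8 for TTGGCGC and 5 of 8 for TTCGCGC.

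EGR1 is a zinc-finger protein of the immediate early response whose fingers read G-rich strands around GTGGGCG. The best word was CCCCCGCA, with an E-score of 0.4801 and a median intensity 9.35 times that of the median 8-mer. CCGCCCCC reached 0.479, CCACCCAC 0.478, CCCCCGTA 0.477 and CACCCACG 0.476. Of the class GTGGGCG, 5 of 8 8-mers were bound, with a median E-score of 0.455. GGGGGCG had 6 of 8 bound and a median of 0.465. With E-scores recomputed from the spot intensities without correction for position, the order of these counts turned, to 6 of 8 for GTGGGCG and 4 of 8 for GGGGGCG, while CCGCCCCC fell to 0.443 and CCCCCGTA to 0.438, below the threshold. GTGGGTG and GTGGGAG had 2 of 8 bound each, with medians of 0.443 and 0.420, and GTGGGTG had 4 of 8 without the correction. All of these medians lay above those of the 10000 matched random sets. In the recomputation without correction, spots tied at the scanner ceiling, 4.63% of those used, were ranked in order of their sequence. The values without the correction can therefore reflect tie order as well as array position. After the neighbourhood division, GTGGGCG had 5 of 8 bound, GGGGGCG 6, GTGGGTG 2 and GTGGGAG 2, as in the deposited scores.

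FOXO3 is a forkhead protein that acts downstream of insulin signalling and reads GTAAACA. All 8 8-mers holding GTAAACA were bound, with a median E-score of 0.492. The best were GTAAACAA, TGTAAACA and CGTAAACA, with E-scores of 0.498, 0.497 and 0.495 and median intensities 3.21, 2.91 and 2.59 times that of the median 8-mer. ATAAACAA and TAAACAAA both had an E-score of 0.494. GTAAACAA, TGTAAACA, ATAAACAA and TAAACAAA were counted in 67, 66, 70 and 67 spots, control sequences included, against 36 for CGTAAACA. Their values may therefore lean on control probes. With the neighbourhood division and no control sequences, 107 8-mers passed on the FOXO3 array and 102 of the 110 recurred. The class ATAAACA was bound in 8 of 8 8-mers, with a median of 0.485. GTAAATA had 5 of 8 bound, and GTCAACA and CAAAACA had 4 of 8 each, which fell to 2 of 8 each when E-scores were recomputed without correction for position. GACGCA, a site read by some other forkhead proteins, had 0 of 48 bound, and its median of -0.159 lay at percentile 39.98 of the random sets, although by median Z-score the class lay at percentile 98.89.

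GATA1 directs red-cell and megakaryocyte development through zinc fingers that recognise GATA. TCTTATCA had an E-score of 0.495 and a median intensity 79.5 times that of the median 8-mer, and AAGATAAG had 0.495 and 77.5 times. AGATAAGC, AGATAAGG and CTGATAAG had E-scores of 0.494, 0.494 and 0.493. With AGATAA, 47 of 48 8-mers were bound, with a median E-score of 0.479. TGATAA followed with 34 of 48 and a median of 0.460, and CGATAA with 27 of 48 and 0.457. GGATAA differs from these only in the base before GATA, and it had 0 of 48 bound and a median of 0.331. AGATTA had 4 of 48 bound, AGATGA 0 of 48 and AGATCT 0 of 26, with medians of 0.421, 0.205 and 0.345. At a threshold of 0.40, AGATTA had 41 of 48 8-mers, CGATAA 47 and GGATAA 7.

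MITF, the master regulator of melanocytes, is a basic helix-loop-helix leucine-zipper protein that binds E-boxes (CANNTG), best with a T before CACGTG. All 26 8-mers with CACGTG were bound, with a median E-score of 0.492. The best were ATCACGTG at 0.498 and CACGTGAC at 0.497, with median intensities 4.49 and 3.49 times that of the median 8-mer. CCACGTGA, AGCACGTG and ACCACGTG had E-scores of 0.496, 0.496 and 0.495. By the base before CACGTG, the median E-score was 0.495 for T, 0.494 for G, 0.490 for C and 0.488 for A, with 8 of 8 8-mers bound in each. CACGTG is its own reverse complement, so these classes share 8-mers. ACACGTGA and CCACGTGA, the best of the A and C classes, also hold TCACGTG on the other strand. The M-box variant CATGTG had 10 of 48 bound. By flank, TCATGTG had 4 of 8 bound, ACATGTG 2, GCATGTG 1 and CCATGTG 0, with medians of 0.453, 0.433, 0.398 and 0.358. CATATG had 2 of 26 bound and CACCTG 1 of 48. Without correction for position these low counts fell, to 1 for CATATG and ACATGTG and 0 for CACCTG and GCATGTG. The remaining E-boxes CATCTG, CAGCTG, CAATTG, CAAGTG, CAACTG and CAAATG had 0 bound.

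Stat3 is a cytokine-activated factor whose phosphorylated dimer grips palindromes with the arms TTC and GAA. The best words were TCCGGGAA and TCCCGGAA, both with an E-score of 0.496 and the former with a median intensity 4.19 times that of the median 8-mer. TACGGGAA, TACCGGAA and CCGGGAAA had E-scores of 0.495, 0.494 and 0.493. All 4 8-mers with TTCCNGGA were bound, with a median E-score of 0.489. The arms at the shorter gap of 2 bases, TTCNNGAA, had 2 of 10 8-mers bound and a median of 0.135, at percentile 99.86 of the random sets. These classes held 6 of the 92 bound 8-mers.

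TCF3, the E2A protein of lymphoid cells, is a basic helix-loop-helix protein without the leucine zipper and binds E-boxes with CC or GC at the centre. All 48 8-mers with CACCTG were bound, with a median E-score of 0.494. ACACCTGC led with an E-score of 0.498 and a median intensity 18.4 times that of the median 8-mer. CAGGTGCG, CACCTGCA, CCAGGTGC and GCACCTGC each had an E-score of 0.497. CACGTG had 23 of 26 bound, CAGCTG 19 of 26 and CATCTG 29 of 48, with medians of 0.478, 0.473 and 0.458. CATGTG, CATATG, CAACTG, CAAGTG, CAAATG and CAATTG had 0 bound. WTCAAAG, the site of the HMG-box protein that shares the alias TCF3, had 0 of 16 bound and a median of -0.0635, at percentile 1.04 of the random sets. The E-boxes held 119 of the 121 bound 8-mers.

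Whether these sites are specific to their factors was asked by scoring the primary class of each factor on all 7 arrays. The class scored highest on its own array for EGR1, FOXO3, GATA1, MITF, Stat3 and TCF3. The exception was the E2F7 class TTCCCGC, which had a median E-score of 0.474 on the E2F7 array and 0.478 on the Stat3 array, with 6 of 8 8-mers bound on both. The Stat3 class TTCCNGGA had a median of only 0.0710 on the E2F7 array. The MITF class TCACGTG had a median of 0.454 on the TCF3 array, with 5 of 8 bound, while the TCF3 class CACCTG had a median of 0.129 on the MITF array. AGATAA reached 0.223 on the FOXO3 array, where E-scores fell with the G+C count (r = -0.842 across 8-mers). Random sets there with the G+C counts of GTAAACA and ATAAACA had medians of 0.153 and 0.251, so 0.223 does not stand out from base composition. GTAAACA scored at most 0.137 away from FOXO3, on the TCF3 array, and GTGGGCG at most 0.124 away from EGR1, on the E2F7 array.

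**Figure D1:**
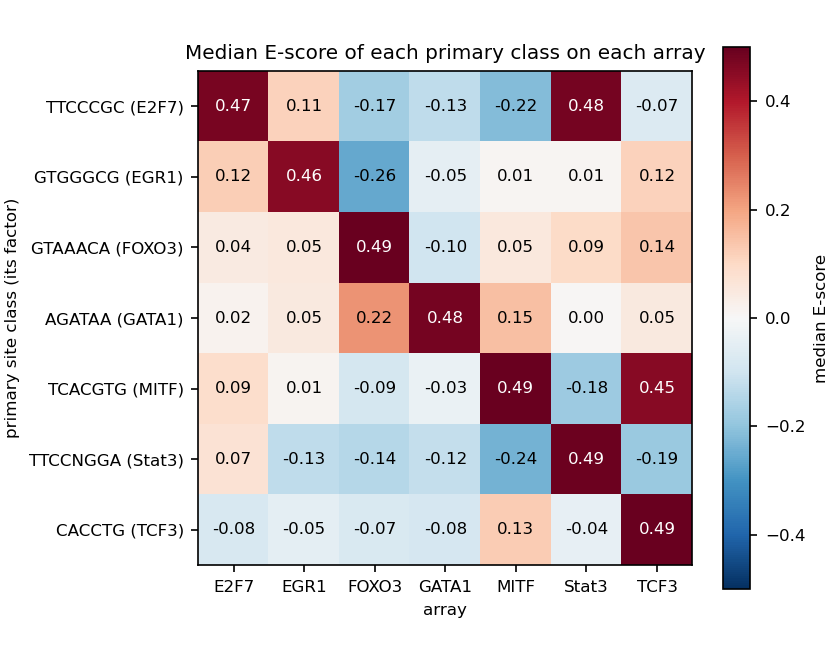
Median E-score of the primary site class of each factor (vertical axis) on each of the 7 arrays (horizontal axis), 1 array per factor, with the colour scale from -0.5 to 0.5. Classes score high on their own array, and TTCCCGC is also high on the Stat3 array (0.478) and TCACGTG on the TCF3 array (0.454).

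Related proteins can bind the same words, so bound lists were compared in all 21 pairs of arrays. MITF and TCF3, both E-box proteins used at the same concentration, shared 24 bound 8-mers, where independent lists of their sizes would share 0.232. The highest-scoring shared words were GCACGTGC, with E-scores of 0.495 on both arrays, ACACGTGC with 0.491 on MITF and 0.490 on TCF3, and CACGTGCA with 0.491 and 0.488. E2F7 and Stat3 shared 4 8-mers against 0.201 for independent lists. These included GCGGGAAA with 0.496 on E2F7 and 0.485 on Stat3, CTTCCCGC with 0.489 and 0.483, and GGCGGGAA with 0.495 and 0.472. FOXO3 and GATA1 shared GATAACAA, with E-scores of 0.464 and 0.481, and GATAAACA, with 0.479 and 0.454, against 0.585 8-mers for independent lists. Bound 8-mers of both factors had a median G+C count of 2, which the number for independent lists does not take into account. The overlap of FOXO3 and GATA1 is therefore not shown to exceed that of lists with like base composition. The other pairs shared 0. Across 8-mers, which are not independent replicates, E-scores of MITF and TCF3 correlated with a Pearson r of 0.383 and a Spearman rho of 0.387. FOXO3 and MITF, which shared 0 bound 8-mers, had an r of 0.533 and a rho of 0.537, but with the G+C count of the 8-mers removed r was 0.281 for FOXO3 and MITF and 0.344 for MITF and TCF3, little above the 0.317 of E2F7 and MITF, 0.308 of E2F7 and Stat3 and 0.307 of EGR1 and TCF3.

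The study's title concerns the effect of sequence variants on factor binding, and the spots allow every single-base change of a site to be measured. A core site was fixed for each factor, positions are counted from 1 at its first base as written, and spots holding the changed core were compared with spots holding the core. Of the 147 changes, 141 lowered the mean log2 intensity in two-sided permutation tests at a Benjamini-Hochberg adjusted p of at most 0.05, 0 raised it, and 6 passed in neither direction. At unadjusted permutation p-values under 0.05 the EGR1 change C6T was added (p = 0.0499) and still 0 were higher. When only sites on the slide-distant side of the probe were used, 134 changes were lower and 2 were higher, both on the EGR1 array. The tests compare spots of the same array, so their p-values measure the spread between spots and not between repeated experiments.

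Arrays differed in how far core spots stood above the rest. Spots with the core exceeded all others by 4.72 on the log2 scale for GATA1, 3.29 for TCF3, 2.83 for EGR1, 1.82 for MITF, 1.41 for Stat3, 1.17 for FOXO3 and 0.80 for E2F7. The median change was -3.19 for GATA1, -3.10 for TCF3, -2.21 for EGR1, -1.50 for MITF, -1.004 for Stat3, -0.84 for FOXO3 and -0.74 for E2F7. At the ceiling lay 43 of the 124 core spots of GATA1, 71 of the 146 of EGR1 and 2 of the 128 of Stat3, so these values are compressed for GATA1 and EGR1 and give no order between arrays.

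In the GATA1 core AGATAAG, the largest falls lay within GAT. With core spots at the ceiling counted at that value, A3C changed the mean by -4.94 (95% bootstrap interval -5.29 to -4.58, 30.7-fold), T4A by -4.89 and G2A by -4.80, each at an adjusted permutation p of 1.13e-05, which corresponds to the smallest raw p these permutations can give, 1e-05. The first position, before GATA, was permissive for T and C, with a change of -0.32 for A1T (-0.69 to 0.05, adjusted permutation p = 0.0887) and -0.49 for A1C (-0.86 to -0.13, adjusted permutation p = 0.00828). In the TCF3 core CACCTGC, C1G, G6C and A2C changed the mean by -3.32, -3.27 and -3.26, nearly the whole excess of core spots over others. The last base lies outside the E-box, and C7G there gave -0.12 (-0.41 to 0.18, adjusted permutation p = 0.434) and C7T -0.38 (adjusted permutation p = 0.0118). C7A at the same base gave -1.60 (adjusted permutation p = 1.13e-05), so it was not neutral for every change.

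In the EGR1 core GTGGGCG, the largest falls came from changes of G to C. G5C changed the mean by -3.17 (-3.52 to -2.84), G3C by -2.98 and G1C by -2.91. T2G, which makes GGGGGCG, gave 0.11 (-0.02 to 0.24, adjusted permutation p = 0.105), and C6G gave -0.10 (-0.26 to 0.07, adjusted permutation p = 0.266). Of the 146 spots with the EGR1 core, 71 lay at the scanner ceiling, which compresses these differences. In a least-squares fit on 6-mers T2G passed as lower (-0.54, adjusted normal-theory p = 0.00489), while with sites far from the slide T2G and C6G both passed as higher (0.22 and 0.23, adjusted permutation p = 0.0225 and 0.0182). In the MITF core TCACGTG, C4A, G5T and C2T inside the E-box gave -1.80, -1.79 and -1.74. The flanking T was the most permissive position, with T1G at -0.36 (-0.69 to -0.03, adjusted permutation p = 0.0477) and T1C at -0.65 (-0.97 to -0.33).

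In the FOXO3 core GTAAACA, the largest falls lay in the AAA run. A5C gave -1.15 (-1.28 to -1.01), A3G -1.11 and A4G -1.10, against -0.36 for C6T and -0.15 for G1A (-0.29 to -0.0047, adjusted permutation p = 0.0483). In the Stat3 core TTCCNGGA, T1C gave -1.41 (-1.61 to -1.21), C4A -1.37 and T1G -1.33. Spots with a changed first base followed by A after the site still hold the core on the other strand and were left out, here and for MITF, so spots with changes of that base also lack this A, and the sizes of these changes are not directly comparable with the others. C3A gave -0.38 (adjusted permutation p = 0.00727) and G7T -0.13 (-0.39 to 0.13, adjusted permutation p = 0.346). In the E2F7 core TTCCCGC, C7A gave -0.82 (-0.999 to -0.642), C5G -0.81 and C5A -0.81, each close to the full excess of core spots. The smallest falls were C4G, which makes TTCGCGC, at -0.26 (-0.45 to -0.07, adjusted permutation p = 0.00762) and T1C at -0.28 (adjusted permutation p = 0.00511). The calls of the small falls C4G and T1C of E2F7, G1A of FOXO3, A1C of GATA1, T1G of MITF, C3A of Stat3 and C7T of TCF3 were each lost under at least 1 other setting, and A1T of GATA1 passed as lower on linear intensities and G7T of Stat3 in the least-squares fit.

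**Figure D2:**
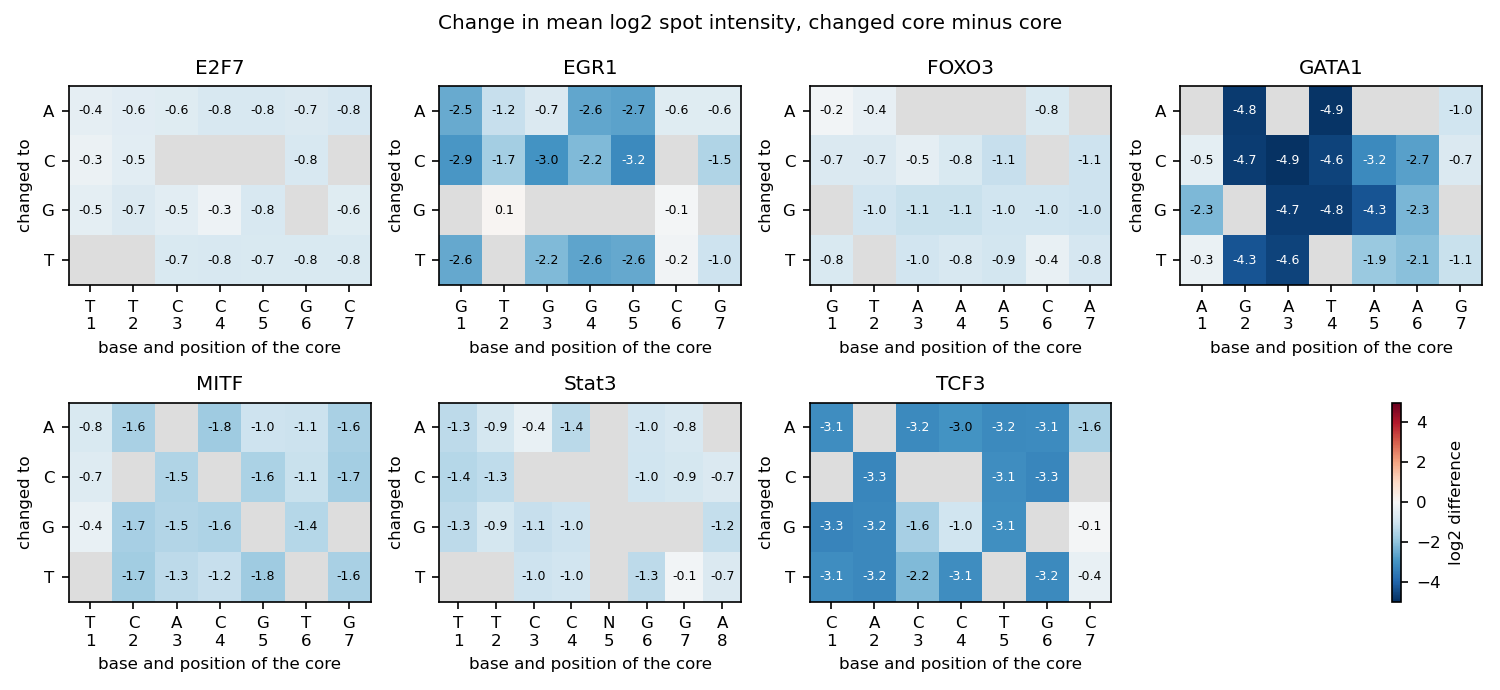
Change in mean log2 spot intensity when a base of the core (horizontal axis, base and position from 1) is replaced by another (vertical axis), with a panel per array and grey for the core's own base or the free base of Stat3. Falls are deepest at the GAT of GATA1, down to -4.94, and some changes of flanking bases are shallow. At the last base of TCF3 C7G is -0.12, while C7A is -1.60.

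MITF and TCF3 belong to the same structural family and were used at 100 nM, so their preferences among the 10 E-boxes were measured on each array against spots with none. On the MITF array CACGTG spots exceeded the others by 1.49 (95% interval 1.34 to 1.63, 306 spots, 2.80-fold), CATGTG by 0.48 (0.43 to 0.54) and CATATG by 0.28. CACCTG followed at 0.13, each of these 4 at an adjusted permutation p of 1.43e-05 over 20 tests. CATCTG at 0.05 (adjusted permutation p = 0.00256) and CAAATG at 0.03 (adjusted permutation p = 0.0283) also passed, but neither did on linear intensities. CAGCTG at -0.04, CAATTG at 0.03, CAAGTG at 0.02 and CAACTG at -0.01 did not, with adjusted permutation p-values of 0.105, 0.148, 0.111 and 0.381. CAATTG passed as higher on linear intensities (adjusted permutation p = 0.0165) and CAACTG as lower with medians (-0.04, adjusted permutation p = 0.0216). Spots were not matched on G+C, and E-scores on this array fell with G+C (r = -0.475 across 8-mers). Among G+C-matched random sets, median E-scores lay at percentile 2.64 for CAATTG, 10.3 for CAGCTG, 10.81 for CAACTG and 30.03 for CAAATG. CAAGTG lay at 90.02 and CATCTG at 100. Apart from CATCTG, these small differences are not told apart from base composition.

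On the TCF3 array all 10 E-boxes passed at an adjusted permutation p of 1.43e-05. CACCTG led at 2.76 (2.65 to 2.87, 632 spots, 6.78-fold), followed by CACGTG at 1.77 (1.64 to 1.90), CAGCTG at 1.48 (1.37 to 1.59) and CATCTG at 0.94 (0.87 to 1.02). CATGTG at 0.41 and CATATG at 0.40 were weak, and CAACTG, CAAGTG, CAAATG and CAATTG lay between 0.14 and 0.23. On spots with no other E-box these fell, to 0.36 for CATGTG, 0.30 for CATATG, 0.15 for CAAGTG and 0.13 for CAACTG. CAATTG fell to 0.08 and CAAATG to 0.07, and each still passed. CAGCTG thus passed as higher for TCF3 and not for MITF, where it passed as lower with neighbourhood-divided intensities (-0.05, adjusted permutation p = 0.00418) and on spots with no other E-box (-0.05, adjusted permutation p = 0.0243). Neither of these lower calls was matched on G+C. The difference between the arrays was not tested, since each factor has 1 array.

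**Figure D3:**
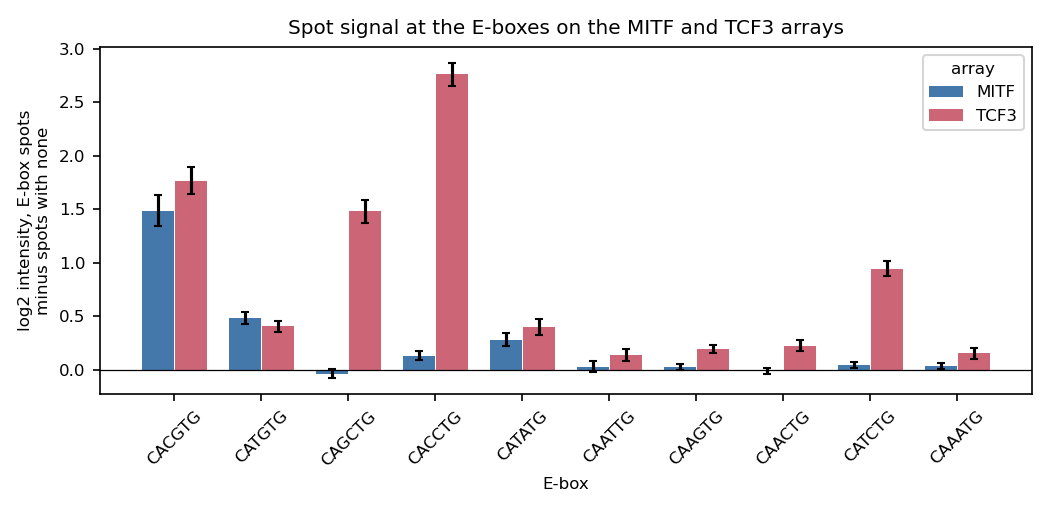
Mean log2 intensity of spots holding each E-box minus that of spots holding none of the 10 (vertical axis) on the MITF and TCF3 arrays, with 95% bootstrap intervals over spots. CACGTG leads on MITF (1.49) and CACCTG on TCF3 (2.76).

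The spacing between the TTC and GAA arms separates the sites of STAT proteins, and gaps of 2, 3 and 4 bases were compared on the Stat3 array. The 3-base gap gave the highest signal, 0.59 above spots with none of these sites on the log2 scale (95% interval 0.47 to 0.72, 285 spots, adjusted permutation p = 1.5e-05). The 2-base gap gave 0.27 (0.20 to 0.35, 293 spots, adjusted permutation p = 1.5e-05). Of the 10 8-mers with this gap 2 were bound, with E-scores from -0.306 to 0.492, so the mean does not hold for all inner bases. The 4-base gap, preferred by STAT6, gave 0.06 (0.01 to 0.12, 272 spots, adjusted permutation p = 0.00809), and it lost significance when medians or linear intensities were compared. Inner bases were not held equal between the gaps, and spots with the 3-base gap had a standard deviation of 1.05. Moreover, 142 spots with TTCCCGC, but with neither TTCCNGGA nor any of these gaps, stood 0.75 above spots with none of these sites. The values therefore do not isolate the effect of the gap.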

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

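All tests in this part were chosen after results had been seen, except those of full Stat3 sites elsewhere in the probes and of the scanner ceiling on the EGR1 array. The tests of an E2F-type protein, of the TTCCCG part and of runs of G were written after lists of bound 8-mers had been looked through, although their own values had not been computed.

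Control probes outside the word-covering design were compared with the median of that design, and series more than 2 times as bright are given here. The factor of 2 was also chosen after the values were seen. On the EGR1 array the series built on Zif268, another name of EGR1, had medians 9.72 times the array median in each of the flank, position, repeat and variant sets, which is the scanner ceiling. Of their spots, 89.4% of the flank set, 76.4% of the position set, 67.3% of the repeat set and 53.2% of the variant set lay at that ceiling. On the same array the repeated homeodomain probe stood at 5.595 times and the homeodomain flank set at 2.57 times. On the FOXO3 array the forkhead position set stood at 3.04 times and the HMG-box position set at 2.49 times. On the GATA1 array the repeated zinc-finger C4 probe stood at 2.36 times and the ETS1 variant set at 2.62 times. On the Stat3 array a homeodomain set stood at 2.07 times. The homeodomain, HMG-box, ETS1 and C4 sets were not examined for chance sites of the factor.

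Probes of 7 control sequences exist with the primer site turned round (reverse-complemented) beside the usual form, and on average they were brighter in the turned form on 5 arrays. Whether the turned probes were double-stranded on the slide is not known, since the Cy3 column could not be used. The geometric mean over the 7 sequences was 1.98 times that of the usual form for E2F7, 2.001 for EGR1, 2.25 for FOXO3, 1.67 for GATA1 and 1.71 for MITF. The EGR1 value is not exact, since the usual form of its Zif268 probe lay at the scanner ceiling. The turned form was brighter in 7 of 7 sequences for E2F7, 6 for EGR1, GATA1 and MITF, and 5 for FOXO3, where it was dimmer for the forkhead probe (3.35 against 5.55 times the array median) and the HMG-box probe (3.29 against 3.48 times). By exact sign-flip tests over the 7 sequences, the lowest p was 0.0156 (E2F7), the smallest that 7 sequences allow, so a single array could not pass on its own after adjustment over 7 arrays. The lowest adjusted p was 0.0729, and these tests leave the differences open. For Stat3 and TCF3 the mean log2 ratios were 0.0317 (95% interval -0.08 to 0.13) and 0.0354 (-0.08 to 0.15). The tables argue against binding to the sites as the source on the FOXO3 array, where the forkhead probe was 1.04 times the median of the other turned probes but 5.74 times that of the others in the usual form. On the EGR1 array, by contrast, the turned Zif268 probe was still 8.32 times the array median. They also argue against the antibody alone, since the lowest mean log2 ratio for an antibody used on several arrays was 0.0317 (Stat3) while E2F7 and MITF, read with the same His antibody, had 0.99 and 0.77. A property of the individual proteins on these probes stays open, and no biological explanation was tested.

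The E2F7 class TTCCCGC scored as high on the Stat3 array as on its own. Full Stat3 sites elsewhere in the same probes are argued against, since 142 TTCCCGC spots without any such site still exceeded spots with neither by 0.75 on the log2 scale (95% interval 0.62 to 0.89). An E2F-type protein on the Stat3 array is argued against by the other E2F classes, TTGGCGC and TTCGCGC, whose higher median E-score there was -0.0149, against 0.4504 and 0.4503 on the E2F7 array. A candidate explanation is that Stat3 binds the TTCCCG part, under which losing the last C should cost little. On the Stat3 array changes of that base moved the mean by 0.21 on average and changes of bases 1 to 6 by -0.67, a ratio of -0.316, while on the E2F7 array the values were -0.73 and -0.63, a ratio of 1.16. The rise on the Stat3 array came mainly from C7G (0.53, adjusted permutation p = 1.11e-05), which brings the site closer to TTCCNGGA, while C7A (-0.10, adjusted permutation p = 0.262) and C7T (0.20, adjusted permutation p = 0.0636) passed in neither direction.

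On the EGR1 array GGGGGCG scored at least as high as the consensus GTGGGCG in the deposited E-scores. In a least-squares fit on 6-mers it passed as lower (-0.54), and with sites far from the slide as higher (0.22). A ceiling that hides a stronger signal of GTGGGCG cannot be told apart from no difference. It would place more GTGGGCG spots at the ceiling, and the share was 48.6% of 146 for GTGGGCG and 56.2% of 146 for GGGGGCG, a difference of -7.53 percentage points (exact Fisher p = 0.241). Runs of G attracting the GST tag or its antibody alike on every GST array are argued against by the other GST arrays. There GGGGGCG had median E-scores of 0.0943 (TCF3) and -0.164 (GATA1). These proteins were used at 100 nM and 65 nM, against 300 nM for EGR1. An attraction that grows with protein concentration is therefore left open. No biological explanation was tested.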

How the results depend on the processing

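Tests on spots holding 1 E-box or 1 gap alone, and E-scores without control sequences, were chosen only after the results were seen. No paired analysis was possible because each factor has 1 array. Another signal column, planned as an alternative, was not run, since the spot tables used here hold no second column for the antibody's dye.

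Of the values that answer a comparison, 126 kept their side and size, 36 moved and 2 lost their call. Bound counts depend on the threshold by construction. In the order E2F7, EGR1, FOXO3, GATA1, MITF, Stat3 and TCF3 they were 153, 348, 295, 531, 153, 222 and 219 at an E-score of 0.40, and 18, 1, 32, 54, 37, 37 and 55 at 0.48. With Z-scores above 4 they were 209, 471, 60, 2794, 157, 353 and 337. For E2F7 the count of 72 fell to 13 when E-scores were recomputed from undivided spot intensities. It was 17 and 41 from the upper and lower rows of the array, also undivided. After the neighbourhood division 83 8-mers passed, and 71 of the 72 recurred. The counts of the other 6 arrays stayed within 1.5 times under these recomputations, but the members changed for EGR1. There 47 of the 78 8-mers recurred from all undivided spots, and 51 and 35 from the upper and lower rows. After the division 78 of 78 recurred. Undivided spots tied at the scanner ceiling were ranked in order of their sequence, so for EGR1 tie order and array position cannot be told apart. On the other 5 arrays at least 72.8% recurred. What the division corrects for on these arrays was not tested.

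Counts of bound 8-mers moved for 20 of the 52 site classes at 0.40, among them GTGGGCG with 8 of 8 and AGATTA with 41 of 48, and for 9 with undivided intensities, among them TTCGCGC with 0, TTGGCGC with 1 and GTCAACA and CAAAACA with 2 each. E2F7 and Stat3 shared 9 8-mers at 0.40, 2 at 0.48 and 12 by Z-score. FOXO3 and GATA1 shared 8 at 0.40 and 0 at 0.48. MITF and TCF3 shared 38 at 0.40, 11 at 0.48 and 47 by Z-score. The number of pairs sharing any 8-mer rose from 3 to 8 at 0.40, 5 with undivided intensities and 14 by Z-score. With undivided intensities the added pairs were EGR1 with MITF and EGR1 with TCF3, sharing 1 8-mer each, where ties at the ceiling also bear on the ranks.

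The total of 141 lowered single-base changes ranged from 134 to 142 over the 6 alternatives, with 2 raised changes only where sites far from the slide were used. Values that reversed were near 0 to begin with. In least squares on 6-mers EGR1 T2G became -0.54 and passed as lower, so GGGGGCG was below GTGGGCG there, while FOXO3 G1A became 0.0296 and did not pass. EGR1 C6G became 0.23 with sites far from the slide, and TCF3 C7G 0.0082 with medians. On the MITF array CAACTG became 42.6 intensity units on the linear scale and CAAATG -0.0026 with medians. The cause was not tested. On the Stat3 array the 4-base gap fell to 0.0209 with medians (adjusted permutation p = 0.316) and was 221 intensity units on the linear scale (adjusted permutation p = 0.0516). On spots with the 4-base gap alone it was 0.07 and passed. The cause was not tested.

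Of the values for single sites and words, 529 kept their side, 57 moved, 13 lost and 7 gained a call in the same direction, and 6 reversed. A lost call is not always a smaller effect. With medians TCF3 C7T was -0.45, against a mean of -0.38. FOXO3 G1A at -0.13 and MITF T1G at -0.22 were smaller with medians than their means of -0.15 and -0.36. Also lost was MITF CAAATG on spots with that E-box alone (0.02, adjusted permutation p = 0.301). Signal over background, as the 99th percentile over the median, was 2.51 to 3.30 on the E2F7, Stat3, FOXO3 and MITF arrays, and its effect on the results was not tested. The ceiling compresses values on the EGR1 and GATA1 arrays, with 71 of 146 and 43 of 124 core spots at it.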

Other observations

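All values in this part were chosen after the data were seen.

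A control series carries the forkhead site in a constant context with every single-base change, 4 spots each. Control sequences entered the recomputed E-scores above, except where left out. Of this series, only the consensus probe was examined on its own above, among the probes with the primer site turned round. On the FOXO3 array its consensus probe stood 5.55 times above the array median. All 21 changes were lower, from -0.55 (A3C) to -2.64 (A4G) on the log2 scale, and G1A was -0.94. Across the 21 changes these differences correlated with those from the word-covering spots at a Pearson r of 0.864 and a Spearman rho of 0.895 (permutation p = 1e-05 for both, the smallest they can give). Without the 2 changes farthest from the median, r was 0.841. The changes share a consensus in each series, so a common error in it would shift all of them alike and leave r unmoved.

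Moving the forkhead site along the probe on the FOXO3 array gave a peak of 5.21 times the array median in the forward strand, at series number 10, with 1.02 times at number 0 and 3.13 times at number 28. In the reverse strand the signal was 1.19 times at number 0, the peak was 3.97 times at number 6, and the signal was 0.998 times the array median at number 24.

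Many bound 8-mers lay outside the fixed classes. For Stat3 these were 86 of 92, and 8-mers holding TTCCCG made up 41 of them, with 43 of all 48 such 8-mers bound. 8-mers holding TTCCGG, counted separately, made up 21. For MITF 24 8-mers lay outside, 11 holding CACGAG and 6 holding CACGCG, led by CTCGTGAC with an E-score of 0.491 and CGCGTGAC with 0.488. For E2F7 58 lay outside, and 13 of 26 8-mers with GCGCGC were bound, with GCGCGCGC at 0.491. For EGR1 63 lay outside, 20 holding CCCCCG and 13 holding CCCACG. For FOXO3 81 lay outside, 20 holding AAACAA and 15 holding ATAACA. For GATA1 12 of 26 8-mers with GATATC were bound, led by CGATATCG at 0.471.

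E-scores fell with the G+C count of the 8-mer on the FOXO3 array, with a Pearson r of -0.842 across 8-mers, and less so on the MITF (-0.475) and GATA1 (-0.413) arrays. 8-mers are not independent replicates. With G+C removed, the correlation of E-scores between FOXO3 and GATA1 went from 0.360 to 0.0125 and that between FOXO3 and MITF from 0.533 to 0.281. That between MITF and TCF3 went from 0.383 to 0.344, and those of E2F7 with MITF and with Stat3 were then 0.317 and 0.308.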
